A study of Homo sapiens with 64 samples.

How the data were processed

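Messenger RNA was measured on 64 bead arrays from U2OS cells with a rat glucocorticoid receptor, in 16 groups of 4 arrays: 4 transfections (NI, siNS, siHic5_2, siHic5_5) by 0, 2, 4 or 24 h of dexamethasone. The labels give 60 pmol of siRNA per well and no dexamethasone dose. Hormone was added 2 days after transfection for the 24 h groups and 3 days after it for the 2 and 4 h groups, and all cells were harvested together. NI is read as cells without siRNA, since the labels name it a noninfected control.

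The deposited values of the 47323 probes are on the log2 scale and were normalized by the authors with a method the labels do not state. The authors name GenomeStudio and limma without saying which step each was used for. The scanner's signals and detection p values were not used, because none of their 128 columns is tied to a sample by any label. For this reason the background correction and quantile normalization planned before the data were examined, and the detection filter, gave way to the deposited values with a filter on their level.

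The background level was the 99th percentile of 437 olfactory receptor probes over all arrays, 6.45. Probes above it on at least 4 arrays were kept, 19020 in all. Of the 47323 probes, 30113 carry a single gene symbol, 8 carry several and 17202 carry none, and 30074 matched the gene annotation used for positions. The probe with the highest mean stood for a gene, which left 15430 features, 11175 of them with a symbol, and 2919 genes had more than 1 probe past the filter. Where a whole group lies below background, the fold is a lower bound against the background level.

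All 64 arrays were fitted in limma 3.58.1 (R 4.3.3, version 1.17.8 of data.table) with a mean per group and moderated variances. Benjamini-Hochberg adjustment was made within each contrast at a threshold of 0.05. The comparisons were each Hic-5 siRNA with siNS at each time, each hormone time with 0 h within a transfection, the difference between responses with each Hic-5 siRNA and siNS, siNS with NI at 0 h, and siHic5_2 with siHic5_5 at 0 h. A depletion, response or difference count needs both siRNAs past the threshold in the same direction. A response counted as absent in siNS when both siRNAs passed in 1 direction, siNS did not, and the average difference of responses passed with each siRNA showing that sign. A response counted as altered when siNS passed and the average difference passed. Because both siRNAs share the siNS arrays, shared counts were set against independent lists, 50 simulations without effect, siNS arrays divided between the siRNAs in 6 ways, and a separate control for siHic5_5.

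The comparisons, the 17 gene lists, the rule for naming genes and the alternatives, apart from those described as added, were fixed before the data were examined. By that rule TGFB1I1 is named throughout, and other genes need a single symbol and no overlap between the arrays of the compared groups. Depletion names the 10 highest and 10 lowest by the smaller of the changes with the 2 siRNAs at 0 h and the 3 highest and 3 lowest later. The siNS response names 8 in each direction at 4 h and 5 at 2 and 24 h. Differences of responses name the 5 largest in each direction, with the called sign in each siRNA in place of the array rule. The control siRNA and siRNA difference comparisons name 3 in each direction, and lists name up to 4 members each by adjusted p. The text gives part of the genes so named. Members of lists that are called with both siRNAs are also given, and these were chosen after their values were seen. Lists were tested with camera at a correlation of 0.01 between genes, with adjustment over 493 tests of lists and contrasts, and with an estimated correlation and fry as alternatives. Means of the GR-induced list per array were compared by exact permutation.

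Alternatives were no filter, a filter at 32 arrays (14372 probes), every probe tested, a block on the replicate number, trend and robust variance, array weights, a fold of at least 1.5, only the arrays compared, NI in place of siNS, separate controls, the average of both siRNAs, and each array left out in turn. Quantile normalization without background correction, detection filters and a slide block were not run, since they need the scanner table. Leaving out siNS arrays that look out of place was added after the data were seen. Replicate numbers were not used as pairs, because the labels state no meaning for them.

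Arrays of a group correlated at 0.971 to 0.989, and the lowest correlation of any 2 arrays was 0.922. The median change over all genes lay between -0.035 and 0.027 in every contrast. The array medians of the deposited values lay between 5.4207 and 5.4236, so the normalization sets this and it is no test for a global shift. The fits were tested on simulated data with the gene means and variances of these arrays and noise drawn independently for each gene and array. In the depletion comparison at 0 h they recovered 34.3% of genes changed by 0.6, 67.2% by 1 and 98.5% by 2 log2 units. For the difference of responses at 4 h these shares were 13.4%, 44.8% and 90.9%, with 0 false calls in either case, and the siNS response at 4 h gave 5 false calls beside 145 recovered genes. The list that was raised was recovered, and 0 of 14 others without shared members were called. Because the simulated genes and arrays are uncorrelated, these false calls and this list check do not give the error rate in the real arrays. Figures were drawn with Python 3.11.15, matplotlib 3.10.9 and numpy 2.4.6.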

Results

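The series measured messenger RNA on 64 whole-genome bead arrays. The cells were a clone of U2OS, a human osteosarcoma line, that stably expresses the rat glucocorticoid receptor. Cells were left without siRNA (NI), or received a nonspecific siRNA (siNS) or 1 of 2 siRNAs against Hic-5 (siHic5_2 and siHic5_5). Hic-5, the product of TGFB1I1, is a LIM domain adaptor of focal adhesions that also acts as a coregulator of steroid receptors. Each transfection was harvested after 0, 2, 4 or 24 h of dexamethasone, a synthetic glucocorticoid, which gives 16 groups of 4 arrays. The study asks which genes need Hic-5 for their normal response to the hormone. Every array held between 14607 and 14615 probes above the background level of 6.45 on the log2 scale. Counts this close reflect the normalization and say nothing on array quality. The number of arrays limits the precision. All gene positions are on GRCh38.p14, and each gene is read from 1 probe.

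The target transcript fell with both siRNAs at every time. TGFB1I1 (chromosome 16, 31472152 to 31477960) averaged 9.45 ± 0.26 in NI and 9.38 ± 0.15 in siNS at 0 h (log2, SD, n = 4). It averaged 5.61 ± 0.43 with siHic5_2 and 5.48 ± 0.43 with siHic5_5, under the background on every array of both groups. It was therefore at least 7.62-fold lower with either siRNA than with siNS (adjusted p = 1.3e-17 and 1.5e-18). After hormone it was at least 6.61-fold lower at 4 h and at least 4.38-fold lower at 24 h with either siRNA. At 2 h the bound was 6.14-fold for siHic5_5, and with siHic5_2, which left 1 of 4 arrays above background, the log2 difference was -3.12 ± 0.23 (SE, adjusted p = 1.8e-14). The TGFB1I1 level of siNS cells was 9.07 ± 0.17 at 2 h, 9.18 ± 0.18 at 4 h and 8.58 ± 0.14 at 24 h of hormone.

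**Figure D1:**
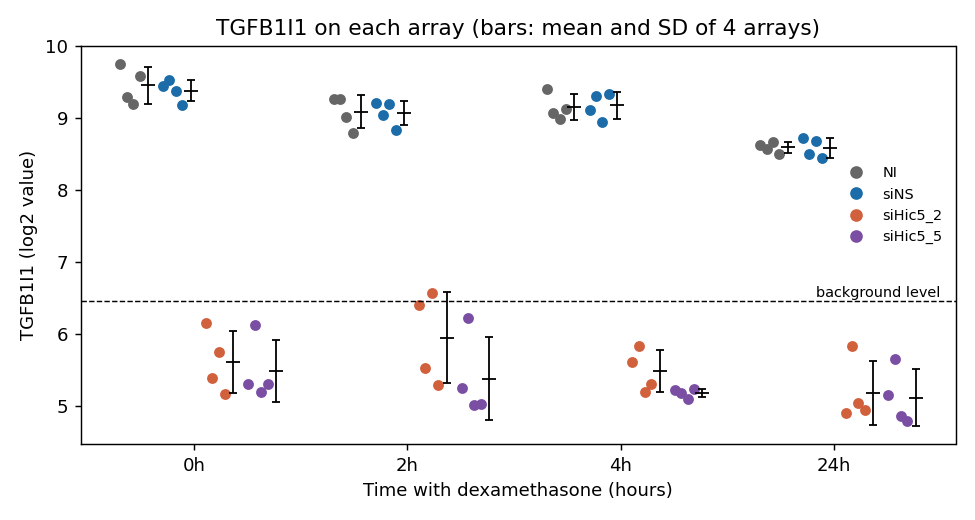
TGFB1I1 on the log2 scale (y axis) on each of the 64 arrays, by transfection and hours of hormone (x axis), with group means and SD. With both Hic-5 siRNAs 31 of 32 arrays lie under the background level of 6.45, and the NI and siNS group means lie between 8.58 and 9.45.

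The comparison of each Hic-5 siRNA with siNS at 0 h asks what depletion does before hormone. Among genes above background on every array, GPNMB, a transmembrane glycoprotein (chromosome 7, 23246775 to 23275108), rose by 1.71 ± 0.26 with siHic5_2 and 1.58 ± 0.26 with siHic5_5 (log2, SE, n = 4 per group, adjusted p = 2.6e-06 and 3.5e-06). HSPB2, a small heat shock protein, rose by 1.57 ± 0.21 and 1.89 ± 0.21 (adjusted p = 1.5e-07 and 6.2e-10). Against NI the HSPB2 rise was smaller, 0.79 and 1.10 (adjusted p = 0.0055 and 3.7e-05), since siNS was lower than NI. PDK4, the kinase that inhibits pyruvate dehydrogenase (chromosome 7, 95583499 to 95596516), went from below background in siNS and NI to 7.41 ± 0.45 with siHic5_2 and 10.98 ± 0.46 with siHic5_5, at least 1.94-fold and 23.1-fold higher (adjusted p = 4.9e-07 and 7.4e-23). F3, the tissue factor that starts coagulation, was above background on 2 of 4 siNS arrays and was higher by 1.51 ± 0.31 and 1.56 ± 0.31 (adjusted p = 0.00038 and 8.7e-05). SNTB1, a syntrophin (chromosome 8, 120535756 to 120812046), was above background on 1 of 4 siNS arrays and was higher by 2.01 ± 0.29 and 2.05 ± 0.29 (adjusted p = 7.2e-07 and 1.3e-07). Against NI the SNTB1 call was lost (0.41 and 0.45, adjusted p = 0.37 and 0.25), since siNS was lower than NI.

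Genes lower than siNS at 0 h included LUM, PDLIM7 and COL3A1. LUM, a collagen-binding proteoglycan (chromosome 12, 91102629 to 91111494), changed by -1.53 ± 0.22 with siHic5_2 and -1.75 ± 0.22 with siHic5_5 (adjusted p = 9.7e-07 and 1.5e-08), and PDLIM7, an actin-associated LIM protein (chromosome 5, 177483394 to 177497604), by -1.50 ± 0.30 and -2.01 ± 0.30 (adjusted p = 0.00022 and 4.5e-07). COL3A1, type III collagen, changed by -2.43 ± 0.36 with siHic5_2, where 2 of 4 arrays stayed above background, and by -1.55 ± 0.36 with siHic5_5 (adjusted p = 1.6e-06 and 0.00062). The transcription factor MITF, with 1 of 4 arrays left above background with each siRNA, changed by -1.62 ± 0.32 and -1.88 ± 0.32, and the cytokine signalling inhibitor SOCS3, with 2 and 1 of 4, by -1.53 ± 0.28 and -1.50 ± 0.28. Against NI the siHic5_2 calls of PDLIM7 and MITF were lost (-0.80 and -0.78, adjusted p = 0.057 and 0.081), and those of LUM, COL3A1 and SOCS3 were kept.

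In all, 678 of 15430 features changed in the same direction with both siRNAs, 394 higher and 284 lower (limma). Independent lists of these sizes would share 391.9, and 389 further features were called in opposite directions. With NI as a separate control for siHic5_5, 455 were shared (409.4 for independent lists) and 608 were opposite, more than shared, and the changes correlated at -0.06 across genes. With the siNS arrays divided between the siRNAs, 289.5 were shared at 0 h (median of 6 splits, 186.8 for independent lists of those sizes). Of the 20 genes the rule named here, 12 were also called in the same direction with both siRNAs against NI, while 6, SNTB1 and HSPB2 among them, had moved the opposite way in siNS against NI.

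Groups of genes fixed beforehand were read from the average of both siRNAs at 0 h. Of 29 measured GR-induced genes, 6 were higher and 0 lower, and 6 and 0 adjusted over the list alone (camera adjusted p = 0.00036, and adjusted p = 0.19 with an estimated correlation). FKBP5, a receptor co-chaperone, rose with both siRNAs, by 0.76 ± 0.19 and 0.85 ± 0.19, and TSC22D3, a glucocorticoid-induced leucine zipper protein, by 0.89 ± 0.17 and 2.29 ± 0.17. ZBTB16, MT1X and PDK4 were the other members that rose with both. Of 4 metallothioneins, 2 were higher, and 2 over the list alone (adjusted p = 0.011, and 0.18 with an estimated correlation). Of 17 p53 targets, 5 were lower, and 6 adjusted over the list alone (adjusted p = 0.0044, and 0.47 with an estimated correlation), and TP53INP1 and DDB2 were lower than siNS with both siRNAs. TP53INP1 was itself called higher in siNS than in NI, so that the shared siNS arrays enter this difference. Of 14 inflammatory genes, 2 were lower, and 4 over the list alone (adjusted p = 0.035, and 0.63 with an estimated correlation). This average covers 2 unlike siRNAs, since 10 of the 14 differed between them and PLAUR alone was lower with both.

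In the average of both siRNAs at 0 h the other lists passed no camera test. Higher and lower members numbered 4 and 1 of 16 apoptosis regulators, 3 and 0 of 18 endoplasmic reticulum stress genes, 2 and 0 of 16 sterol synthesis genes, and 2 and 2 of 19 immediate-early genes. The apoptosis inhibitor BCL2 rose by 1.31 ± 0.27 and 1.35 ± 0.27. Matrix and TGF-beta targets had 0 higher and 3 lower of 20, interferon genes 0 and 2 of 14, circadian genes 0 and 1 of 13, and steroid receptors and coregulators 1 and 2 of 17. Osteoblast markers had 1 and 0 of 7, epithelial markers 1 and 0 of 5, leukocyte markers 0 and 0 of 6, and cell cycle genes 0 and 0 of 23. Counts adjusted over the list alone were equal to these. Focal adhesion genes had 1 higher and 3 lower of 22, and 1 and 5 adjusted over the list alone. For this list too the average covers unlike siRNAs, since most of the 22 differed between them, as given below. The matrix list had a median of 0.07 and a mean of -0.13, the immediate-early list a median of 0.01 and a mean of -0.03.

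Depletion and siNS cells were also compared at each time after hormone. At 2 h ITGB8, an integrin subunit below background in siNS, was at least 1.55-fold higher with siHic5_2 and 4.04-fold higher with siHic5_5 (adjusted p = 2.5e-05 and 1.1e-11), and ID1, an inhibitor of helix-loop-helix factors, was lower by -1.90 ± 0.32 and -2.84 ± 0.32 (adjusted p = 1.9e-05 and 1.1e-09). At 4 h NEU4, a sialidase, was at least 3.69-fold and 4.73-fold higher, and ST6GALNAC5, a sialyltransferase, was at least 2.65-fold lower with either siRNA. At 24 h SCGB2A1, a secretoglobin, was higher by 3.13 ± 0.19 and 2.99 ± 0.19 (adjusted p = 3.3e-18 and 2.4e-17, 3 of 4 siNS arrays above background). Of 22 focal adhesion genes, PARVA, ITGB5, BCAR1, SRC, ACTN1, ACTN4 and TRIP6 were lower with both siRNAs at 24 h. In the average of both siRNAs 9 were lower and 2 higher, and 9 and 3 adjusted over the list alone (camera adjusted p = 0.016, and 0.28 with an estimated correlation). The shared counts were 749 at 2 h (424 higher), 1114 at 4 h (580 higher) and 1019 at 24 h (512 higher), and independent lists would share 419.2, 565.5 and 568.1. Against siNS 416, 437 and 544 features were called in opposite directions. With NI as the separate control, 507, 755 and 795 were shared (429.1, 573.2 and 604.8 for independent lists) and 656, 716 and 779 were opposite, more than shared at 2 h.

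The response of siNS cells to dexamethasone gives the reference for the study's question. At 4 h FAM90A1 was at least 24.1-fold higher and PDK4 at least 25.7-fold higher than at 0 h, where both were below background (adjusted p = 1.3e-17 and 2.0e-23). TIPARP, an ADP-ribosyltransferase, rose by 3.91 ± 0.26 and TSC22D3 by 2.97 ± 0.17 (log2, SE, n = 4, adjusted p = 6.3e-17 and 3.4e-19). The growth factor HBEGF changed by -3.43 ± 0.51 and the early response gene IER3 by -3.16 ± 0.37 (adjusted p = 1.2e-06 and 4.7e-09). The cytokines IL11 and LIF fell below background, to at least 2.98-fold and 4.75-fold lower. At 2 h TXNIP, a thioredoxin inhibitor, was already higher by 3.42 ± 0.29 (adjusted p = 1.6e-13), with TIPARP at 3.69 ± 0.26 and HBEGF at -3.32 ± 0.51.

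At 24 h the largest increases in siNS included SPINK13, a protease inhibitor family member that rose at least 33.1-fold, and SLN, the calcium pump regulator sarcolipin, at 5.48 ± 0.33 (adjusted p = 1.4e-18 and 3.3e-19). The chemokine CCL2 and the tight junction gene CLDN1 fell at least 15.0-fold and 7.51-fold (adjusted p = 4.4e-06 and 8.7e-14), and the keratin KRT80 changed by -4.17 ± 0.31 (adjusted p = 5.9e-16). Of 29 GR-induced genes, 12, 15 and 20 were higher at 2, 4 and 24 h and 0 were lower, and 14, 17 and 21 were higher adjusted over the list alone, with 0, 1 and 0 lower. Camera gave adjusted p = 1.0e-22, 1.3e-23 and 2.6e-15, and adjusted p = 2.5e-05, 2.0e-05 and 0.00058 with an estimated correlation. Of 14 inflammatory genes, 2, 5 and 10 were lower and 0 higher, and 5, 5 and 11 were lower adjusted over the list alone (at 24 h camera adjusted p = 3.9e-06, and 0.19 with an estimated correlation). Of 23 cell cycle genes, 15 were lower at 24 h, and 16 over the list alone, for example MCM2 by -1.53 ± 0.23 and CDK1 by -1.24 ± 0.20 (camera adjusted p = 3.6e-08, and 0.39 with an estimated correlation).

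The features called in siNS numbered 562 at 2 h (300 higher), 931 at 4 h (509 higher) and 4462 at 24 h (2220 higher). NI cells gave 430, 1029 and 5392. Of these, 336, 656 and 3662 were shared in direction with siNS and 0 were opposite, where independent lists would share 7.89, 31.5 and 780. Tested directly, the response differed between siNS and NI for 0, 0 and 1 features (limma). The siNS arrays numbered 2 at 2 and 4 h scored with the other time, as described below, and enter the siNS counts. Without that array the siNS count fell below the NI count at 2 h and rose above it at 4 h. Fewer arrays also change a count by themselves. The higher siNS count at 2 h and the lower one at 4 h therefore do not show that siNS and NI responses differed. Called with both Hic-5 siRNAs were 292, 933 and 3201 features, of which 217, 522 and 2467 were shared with siNS and 0, 0 and 6 were opposite. Over features called in NI, the median change in siNS, siHic5_2 and siHic5_5 was 1.24, 1.04 and 0.78 for increases and -0.87, -0.70 and -0.77 for decreases at 2 h. At 4 h it was 0.86, 0.85 and 0.80 and -0.70, -0.75 and -0.80, and at 24 h 0.64, 0.67 and 0.58 and -0.62, -0.71 and -0.59, so that neither Hic-5 siRNA had a smaller median change than siNS in every class. Fitted on their own arrays alone, the siNS groups gave 223 features at 2 h and 402 at 4 h.

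**Figure D2:**
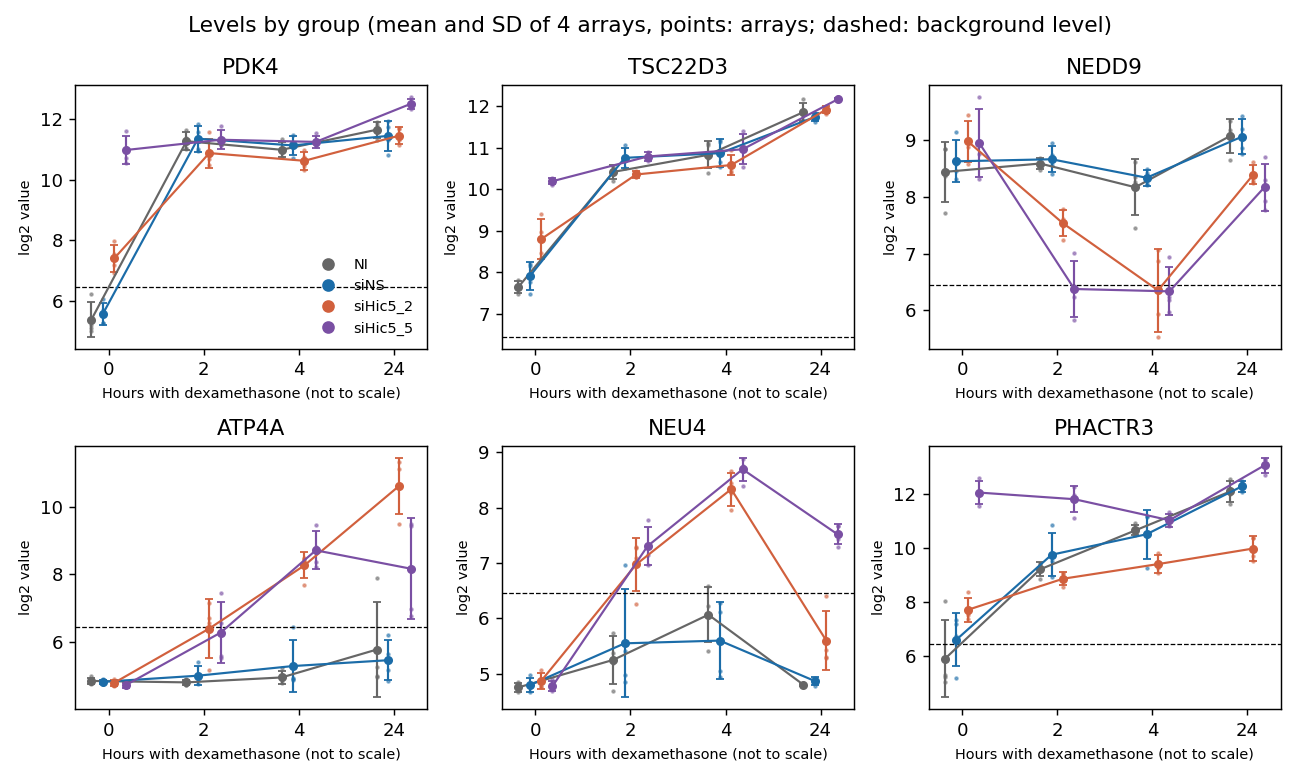
Log2 values (y axis) of PDK4, TSC22D3, NEDD9, ATP4A, NEU4 and PHACTR3 on each array by transfection and hours of hormone (x axis), with group means. PDK4 starts at 5.58 in siNS and 10.98 with siHic5_5 at 0 h, and reaches 11.13 and 11.25 at 4 h.

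The central question is whether the hormone response itself differed with Hic-5 depleted, tested as the difference between responses. PDK4, TSC22D3 and F3 had smaller responses with depletion, and each started from a higher level. TSC22D3 (chromosome X, 107713221 to 107775988) rose by 2.97 ± 0.17 in siNS at 4 h, by 1.79 ± 0.17 with siHic5_2 and by 0.77 ± 0.17 with siHic5_5, an average difference of -1.69 ± 0.21 (adjusted p = 6.2e-07). Its levels at 4 h were 10.87, 10.58 and 10.96, and at 0 h 7.90, 8.80 and 10.19. PDK4 differed by -3.81 ± 0.31 at 4 h (adjusted p = 1.3e-12), a value that rests on siNS levels under background at 0 h. F3 rose by 2.85 ± 0.31 in siNS at 4 h and by 1.01 ± 0.31 and 0.94 ± 0.31 with the siRNAs (difference -1.87 ± 0.38, adjusted p = 0.0042). TMEM100 started at similar levels in siNS and siHic5_2, 8.39 and 8.37, and at 9.62 in siHic5_5, and rose by 2.08 ± 0.20 in siNS against 0.39 ± 0.20 with siHic5_2 and -0.16 ± 0.20 with siHic5_5 (difference -1.97 ± 0.25, adjusted p = 8.4e-07).

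At 2 h 3 features passed with both siRNAs, and all are named: PDK4, TSC22D3 and BCL11A. Fitted on the arrays compared alone, this count was 0 (limma, 127 at the unadjusted level). BCL11A, a zinc finger repressor, changed by -1.37 ± 0.15 in siNS and by -0.19 ± 0.15 and -0.15 ± 0.15 with the siRNAs (differences 1.18 ± 0.21 and 1.21 ± 0.21, adjusted p = 0.0023 and 0.00048). The counts were 18 at 4 h (10 with a positive and 8 with a negative difference) and 119 at 24 h (57 and 62). A positive difference can be a larger increase or, as for BCL11A, a smaller decrease, so these signs do not count larger and smaller responses. At 24 h CIDEC, a lipid droplet protein, rose at least 9.24-fold in siNS and was under background on all siHic5_2 arrays and on 2 of 4 siHic5_5 arrays (adjusted p = 2.8e-07 for the difference). In the other direction SAG, the retinal arrestin, rose at least 1.58-fold in siNS, with 3 of 4 arrays above background, against at least 12.3-fold and 16.8-fold with the siRNAs (adjusted p = 6.0e-06 for the difference, which like that of CIDEC rests on 0 h values under background). Independent lists would share 0.0078, 0.22 and 10.9 features at 2, 4 and 24 h. Because both siRNAs are compared with the same siNS arrays, the counts with siNS split between them were 1, 3.5 and 40 (medians of 6 splits, 0.0013, 0.025 and 3.16 for independent lists). With NI as a separate control for siHic5_5 they were 3, 18 and 88 (0.0096, 0.19 and 12.8 for independent lists), with 0, 0 and 19 opposite.

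Features that responded with both siRNAs and were not called in siNS numbered 5 at 2 h (3 higher), 44 at 4 h (32 higher) and 107 at 24 h (59 higher). NEDD9, a focal adhesion scaffold (chromosome 6, 11183298 to 11382348), changed by -2.62 ± 0.28 with siHic5_2 and -2.61 ± 0.28 with siHic5_5 at 4 h (adjusted p = 1.7e-10 and 2.2e-10), with 2 and 1 of 4 arrays left above background. In siNS and NI it changed by -0.29 ± 0.28 and -0.27 ± 0.28 (adjusted p = 0.76 and 0.77), and the difference was -2.32 ± 0.34 (adjusted p = 2.0e-05). ATP4A, the gastric proton pump subunit (chromosome 19, 35550031 to 35563658), was below background at 0 h and rose at least 3.52-fold and 4.79-fold at 4 h with the siRNAs, while 1 siNS and 0 NI arrays exceeded background (adjusted p = 0.0008 for the difference, which rests on values under background). KLF9, a GR-induced list member that encodes a Kruppel-like factor, changed by -1.12 ± 0.21 and -0.77 ± 0.21 with the siRNAs and by 0.27 ± 0.21 in siNS (difference -1.22 ± 0.25, adjusted p = 0.0047). At 24 h NNMT, which methylates nicotinamide, changed by -2.09 ± 0.17 and -1.57 ± 0.17 with the siRNAs against -0.41 ± 0.17 in siNS (difference -1.42 ± 0.21, adjusted p = 7.3e-06).

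All 5 genes at 2 h are named. NEDD9 differed by -2.04 ± 0.34 and RASSF5, a Ras association domain protein, by 1.05 ± 0.19 (adjusted p = 0.00061 and 0.002), and ID3 by -1.31 ± 0.28 (adjusted p = 0.019). TAMALIN rose at least 1.76-fold and 2.27-fold with the siRNAs and NEU4 at least 1.44-fold and 1.81-fold, each with 3 of 4 siHic5_2 arrays above background (adjusted p = 0.038 and 0.033 for the differences, which rest on values under background). The calls of TAMALIN and NEU4 ended without the siNS 2 h array numbered 4 (adjusted p = 0.21 and 0.18), and that of ID3 without the siNS 2 h array numbered 2 (adjusted p = 0.075). Not every gene of this group was silent in both controls: NEU4 was called in NI at 4 h, where 1 array exceeded background (adjusted p = 0.00099).

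Features called in siNS whose response differed with depletion numbered 18 at 2 h (15 smaller), 51 at 4 h (28 smaller) and 274 at 24 h (162 smaller). Smaller here means that the average difference runs against the siNS response, which includes responses that reversed, such as that of ADRA1B. Only the average of both siRNAs had to pass, so 1 siRNA alone can carry a call. PHACTR3, a phosphatase and actin regulator, rose by 5.65 ± 0.42 in siNS at 24 h, and by 2.26 ± 0.42 with siHic5_2, against 1.01 ± 0.42 with siHic5_5 (adjusted p = 0.059, difference -4.02 ± 0.51, adjusted p = 4.0e-07). Its level at 0 h was 6.62 in siNS, with 3 of 4 arrays above background, 7.72 with siHic5_2 and 12.04 with siHic5_5. ADRA1B, an adrenergic receptor, rose by 0.91 ± 0.30 in siNS and changed by -1.95 ± 0.30 and -1.68 ± 0.30 with the siRNAs at 24 h (difference -2.73 ± 0.37, adjusted p = 1.2e-06). Larger responses included FHDC1 at 4 h, at least 1.71-fold in siNS and at least 5.13-fold and 8.53-fold with the siRNAs (adjusted p = 6.5e-05 for the difference, with 0 h values under background). MYC, an immediate-early list member, changed by -0.91 ± 0.22 in siNS at 4 h and by -1.71 ± 0.22 and -2.70 ± 0.22 with the siRNAs (difference -1.30 ± 0.27, adjusted p = 0.0056). The count at 2 h was 11 without the siNS 0 h array numbered 2, that at 4 h was 29 without either the siNS 0 h array numbered 4 or the siNS 4 h array numbered 3, and that at 24 h was 177 without the siNS 0 h array numbered 4.

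As a group, the GR-induced list responded less with depletion at 2 and 4 h. In the average difference between responses at 4 h, 4 of 29 members were lower and 0 higher, and 12 lower and 1 higher adjusted over the list alone. The median difference was -0.55 (camera adjusted p = 1.4e-15, and 0.00055 with an estimated correlation). At 2 h 2 members were lower, and 10 over the list alone (adjusted p = 7.8e-22, and 3.1e-05 with an estimated correlation), and at 24 h 6 were lower, and 8 over the list alone (adjusted p = 1.4e-06, and 0.089 with an estimated correlation). Averaged over the list, arrays held 8.63 ± 0.11 in siNS at 0 h, 8.45 ± 0.24 in NI, 8.90 ± 0.13 with siHic5_2 and 9.29 ± 0.22 with siHic5_5 (log2, SD, n = 4). The siHic5_5 level exceeded that of siNS (exact 2-sided permutation p = 0.0286, the smallest possible with 4 against 4), and for siHic5_2 p was 0.0571. At 4 h the averages were 9.79 ± 0.13, 9.70 ± 0.07, 9.59 ± 0.08 and 9.73 ± 0.06, and against siNS exact permutation p was 0.0857 for siHic5_2 and 0.457 for siHic5_5.

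**Figure D3:**
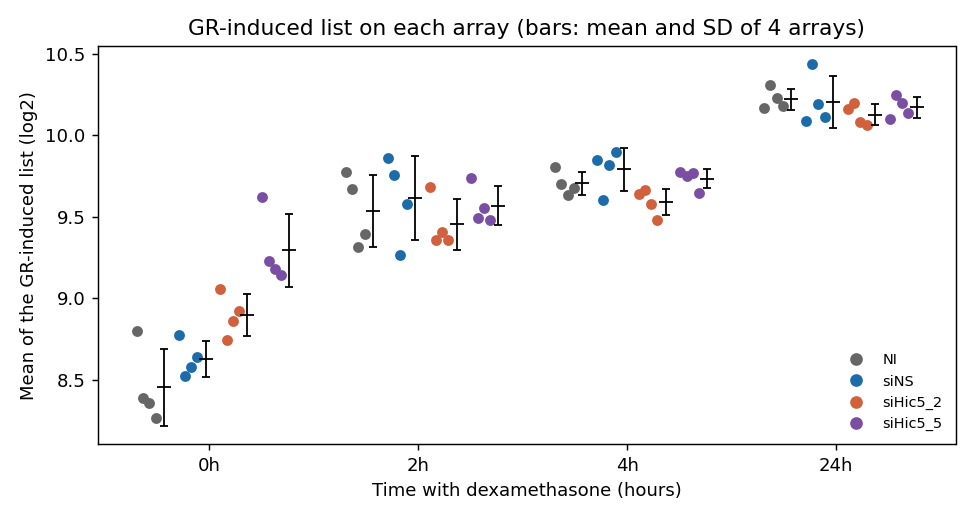
Mean log2 value of the 29 GR-induced genes (y axis) on each array by transfection and hours of hormone (x axis), with group means and SD. At 0 h the siHic5_5 mean of 9.29 lies above the siNS mean of 8.63, and at 4 h the 4 means lie between 9.59 and 9.79.

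The comparison of siNS with NI at 0 h asks how cells with the nonspecific siRNA differ from cells without siRNA. No group was transfected without siRNA, so effects of the siRNA and of transfection cannot be told apart. C1orf54 was at least 1.81-fold higher in siNS and PRPH, the intermediate filament peripherin, at least 1.21-fold higher, with 2 of 4 siNS arrays above background (adjusted p = 0.001 and 0.0018). SNTB1 was lower by -1.61 ± 0.29, with 1 of 4 siNS arrays above background (adjusted p = 0.0028). Of 17 p53 targets, 4 were higher and 0 lower, and 9 and 0 adjusted over the list alone (camera adjusted p = 3.6e-08, and 0.14 with an estimated correlation), TP53INP1 among them (adjusted p = 0.0088). In all, 202 features were called at 0 h, 107 higher and 95 lower, and 148, 375 and 0 at 2, 4 and 24 h. At 24 h the siNS arrays numbered 2 and 3 lay near NI on the siNS minus NI score described below (0.24 and 0.02). Those numbered 1 and 4 reached 1.03 and 1.37. The 0 at 24 h therefore does not show that the difference was gone. The 0 h count was 1111 without the siNS array numbered 2, and 121, 38 and 42 without the NI arrays numbered 1, 3 and 4. It was 59, 16 and 24 without the siNS arrays numbered 1, 3 and 4. Fitted on the 8 arrays at 0 h alone it was 0, where limma gave 2185 at the unadjusted level.

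The siRNAs against Hic-5 also differed from each other at 0 h, in 5983 features, 2942 higher with siHic5_2 and 3041 higher with siHic5_5. AKR1C4, an aldo-keto reductase of steroid metabolism, was lower by -3.97 ± 0.32 with siHic5_2 than with siHic5_5, at -1.16 ± 0.32 and 2.81 ± 0.32 against siNS (adjusted p = 1.5e-14 for the difference). The chemokine CXCL14 was higher by 4.68 ± 0.63 with siHic5_2, with 1 of 4 siHic5_5 arrays above background, and CCL2 by 4.30 ± 0.84 (adjusted p = 2.4e-08 and 3.8e-05). Of 14 inflammatory genes, 10 were higher with siHic5_2 and 0 lower, the same counts as adjusted over the list alone (camera adjusted p = 0.0015, and 0.39 with an estimated correlation). Of 22 focal adhesion genes, 15 were higher and 3 lower, again with equal counts over the list alone (adjusted p = 0.0013, and 0.14 with an estimated correlation). Against siNS, siHic5_2 alone called 2577 features and siHic5_5 alone 4693, and their log2 changes correlated across genes at 0.14. A shared control alone gave 0.50 in simulations without siRNA effects. These are not like values, since changes made by 1 siRNA alone lower a correlation. The covariance exceeded the simulated one by 0.0104, but with NI as a separate control for siHic5_5 the covariance was -0.016. Genes are not independent replicates.

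**Figure D4:**
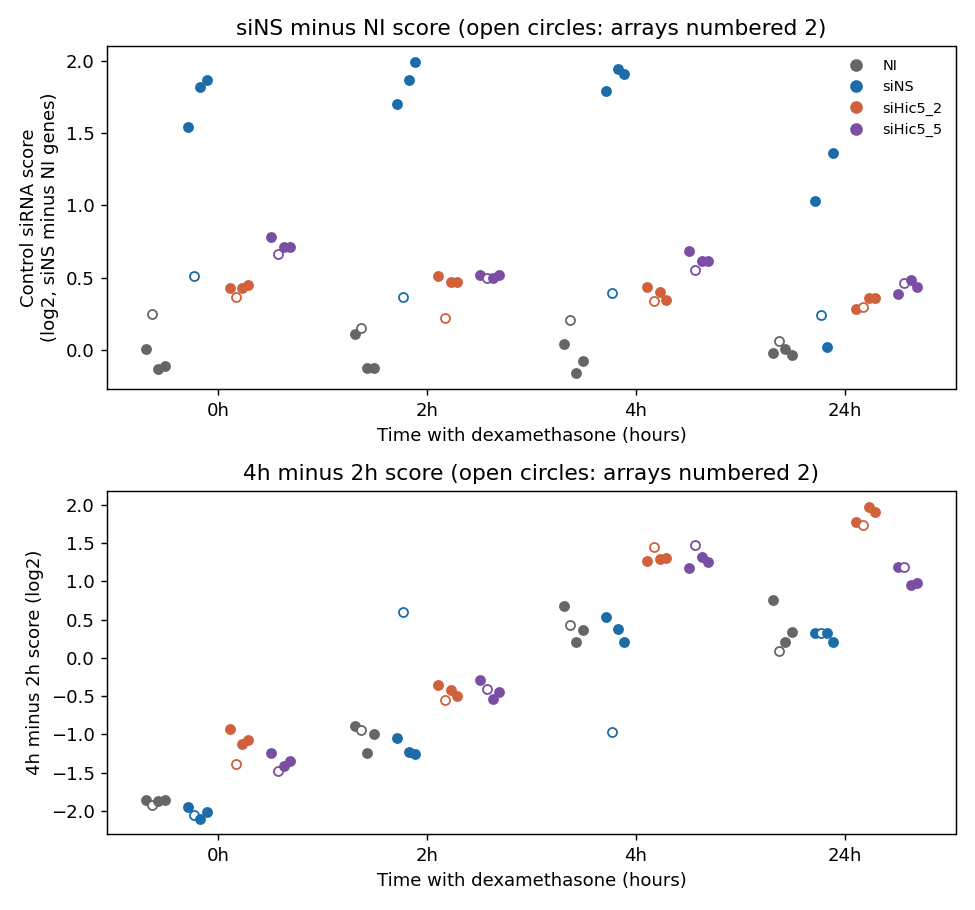
Scores of the 64 arrays for the siNS minus NI difference and for the 4 h minus 2 h difference, by transfection and hours of hormone. On the control siRNA score 11 siNS arrays lie between 1.03 and 2.00, and 5 siNS arrays between 0.02 and 0.51, near the NI arrays.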

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

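The tests of exchanged labels, slow response, exchange with NI, untransfected RNA, doubtful siNS arrays, signal ceiling and starting level were chosen after the result was seen, and the tests of siRNA delivery and of other splits before.

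Arrays were scored by 100 genes per direction for 4 h minus 2 h of hormone, chosen in the other transfections. The siNS 2 h array numbered 2 scored 0.60 where the other siNS 2 h arrays scored -1.25 to -1.05, and the siNS 4 h array numbered 2 scored -0.97 where the others scored 0.21 to 0.54. A candidate explanation is that these labels were exchanged: 2 of the 2 arrays lie nearer the mean of the other time. A slow hormone response in the culture numbered 2 would have lowered the 2 h score, which was 0.598, above every other siNS 4 h array, and so it is argued against. No other biological explanation was tested, and the labels were kept as deposited.

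On a score for siNS minus NI, 11 siNS arrays reached 1.03 to 2.00 and 5 reached 0.02 to 0.51, those numbered 2 at each time and that numbered 3 at 24 h. An exchange with NI arrays is argued against, since the highest NI score was 0.248. Weak siRNA delivery in the cultures numbered 2 may remain: the Hic-5 siRNA shift of arrays numbered 2 was 0.655 to 0.802 of that of the others, lower in 8 of 8 groups but not by as much as in siNS. Untransfected RNA under a siNS label also stays open: 4 of the 5 arrays lie above the highest NI array of their time, but the NI array numbered 2 was itself the highest NI array at 4 of 4 times. For the arrays numbered 2 these cannot be told apart here, while weak delivery in the cultures numbered 2 does not cover the siNS 24 h array numbered 3, and no biological explanation was tested.

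The GR-induced list, which holds receptor targets such as TSC22D3, PDK4 and FKBP5, responded less at 4 h with both Hic-5 siRNAs, by a median of -0.55. The siNS arrays in doubt are argued against as its source, since the median with NI in place of siNS was -0.618 and 24 of 29 members were lower. A signal ceiling is argued against as the whole source, since the 19 members with every group mean under 12 had a median of -0.432, against -0.878 for the others. A higher level before hormone alone may account for it: the median siHic5 minus siNS difference was 0.25 at 0 h and -0.19 at 4 h. The siNS 4 h array numbered 2, which is in doubt, held a list mean of 9.60 and enters the siNS side. At 4 h the siHic5_2 list mean differed by -0.20 from siNS and by -0.11 from NI (exact permutation p = 0.0857 for each). For siHic5_5 the differences were -0.06 and 0.03 (exact permutation p = 0.457 and 0.514). That leaves open whether depletion lowers the final level, and a need for Hic-5 at these promoters is an untested biological explanation.

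TGFB1I1, array scores, the GR-induced list mean and named genes were tested within groups of 4 arrays, 153 tests in all. In 14 of them an array lay far from the other 3. Chance gives about 1 in 20 for a single test, but these tests reuse the same 16 groups and are not independent. Array numbers carry no stated meaning. The gap over the range was 0.889 and 0.861 for TGFB1I1 with siHic5_5 at 0 h (array 2 at 6.12, others 5.20 to 5.30) and siHic5_2 at 24 h (array 2 at 5.84, others 4.90 to 5.03). It was 0.890 for the time score of siNS at 2 h, 0.963 for that of siNS at 24 h (array 4), 0.901 for the siNS minus NI score of siNS at 4 h, 0.857 for that of siHic5_2 at 2 h (array 2), and 0.852 for the GR-induced list mean of siHic5_2 at 2 h (array 1 at 9.69, others 9.36 to 9.41). Among named genes it was 0.846 for HSPB2 (8.81), 0.858 for IFT27 (8.17) and 0.836 for GPRC5A (7.36) on the siNS 0 h array numbered 2, 0.873 for SPINK13 (7.56) and 0.889 for LIF (5.73) on the siNS 4 h array numbered 2, 0.877 for SOCS3 (7.48) on the siHic5_5 0 h array numbered 2, and 0.935 for RGS4 (10.49) on the siNS 0 h array numbered 1.

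The Hic-5 siRNAs differed from each other at 0 h in 5983 features, and 389, 416, 437 and 544 features were called in opposite directions against siNS at 0, 2, 4 and 24 h. The response to hormone differed with both siRNAs for 3, 18 and 119 features at 2, 4 and 24 h, and between siNS and NI for 0 and 0 features at 2 and 4 h (limma) and 1 at 24 h.

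Other splits of the same arrays argue against chance for the hormone responses: the real split alone gave as many calls among 35 for siNS (562, 931 and 4462, highest other 202, 655 and 2233) and for NI (430, 1029 and 5392, highest other 16, 55 and 975), and among 100 for both Hic-5 siRNAs (292, 933 and 3201, highest other 0, 108 and 736). The same holds for the siRNA difference (1 of 35 splits, 5983 against 2502). With 35 splits the smallest possible share is 1 in 35, so they cannot exclude chance. For depletion at 0 h 2 of 100 splits gave as many, the real 678 and another with 2013. These splits exchange arrays of siRNAs that differ in 5983 features at 0 h. A split that gathers 1 siRNA as the control therefore carries real differences, and chance is left undecided. With NI as the separate control for siHic5_5, 455 features were shared at 0 h, against 409.4 for independent lists, and 608 were opposite. Chance is not excluded for siNS against NI (2 of 35, 202 against 745). The splits leave chance undecided for depletion at 2, 4 and 24 h (5, 5 and 6 of 100, 749, 1114 and 1019 against 3566, 2603 and 3468, median of the other splits 0). They exchange arrays of siRNAs that differ in 6161, 6031 and 6260 features at these times, so splits that gather 1 siRNA as the control carry real differences. The same limit holds for the difference of responses at 2, 4 and 24 h (7, 5 and 7 of 100, highest other 1914, 885 and 777), for responses absent in siNS (5, 44 and 107, reached by 6, 6 and 8 of 100, highest other 30, 343 and 599) or for altered responses (18, 51 and 274, reached by 12, 19 and 7 of 100, highest other 2280, 1879 and 2231). For these too the median of the other splits was 0, and which arrays each split places together was not recorded.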

How the results depend on the processing

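The alternatives that leave out siNS arrays in doubt were chosen after the result was seen, and the others before. TGFB1I1 stayed past the threshold in all 142 refits, and neither it nor any named gene changed direction in a refit. Only array weights and left-out arrays could change a direction. The other refits read the same probe with the same group means, and other probes of a gene were not compared in them. The alternatives with NI, separate controls or the average of both siRNAs refitted counts only, not TGFB1I1 or named genes. Of refits of counts, 564 stayed within 1.5 times the count from all arrays and 69 moved, and of refits of named genes, 13540 kept their call or lack of it, 955 lost it and 11 gained one. For the moved counts the cause was not tested, except that fewer arrays, a fold limit or another rule change the calls by construction. Below, D is depletion, E the difference of responses, B responses absent in siNS, A altered responses and C siNS against NI. With no filter B was 3 at 2 h and C 91, and with the stricter filter B was 3 at 2 h. With the replicate block E was 5, 34 and 180 at 2, 4 and 24 h, B 9 at 2 h, A 444 at 24 h and C 612. With array weights D was 1282 and 1369 at 0 and 2 h, the NI response 733 at 2 h, E 11, 48 and 231, B 10 and 197 at 2 and 24 h, A 29, 107 and 483, and C 2183. With a fold of at least 1.5 D was 372, 409, 648 and 601. With only the arrays compared D was 408 and 469 at 0 and 2 h, the siNS response 223 and 402 at 2 and 4 h, B 2 and A 6 at 2 h, A 173 at 24 h, and E at 2 h and C were 0 and 0 (limma, 127 and 2185 unadjusted). With NI in place of siNS B was 14 at 2 h. With the average of both siRNAs D was 2736, 2964, 3657 and 3409, and E 24, 111 and 453. Of 493 list tests 112 passed, 8 with an estimated correlation, all of the GR-induced list, and 189 with fry.

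Leaving out each array in turn, C ranged from 16 to 1111, E at 2 h from 2 to 6, B at 2 h from 2 to 7, and A from 11 to 21, 29 to 73 and 177 to 322 at 2, 4 and 24 h. E at 2 h was 5, 6 and 5 without siNS 0 h array 1, siHic5_2 0 h array 2 and siHic5_2 2 h array 2. B at 2 h was 2 without siNS 0 h array 2, and 3 without siNS 0 h array 4, siNS 2 h array 4, siHic5_2 2 h arrays 1 or 3, or siHic5_5 2 h array 1. Without the siNS arrays numbered 2 at 2 and 4 h, B was 8 at 2 h, and E 30 and A 81 at 4 h. Without those numbered 2 at all 4 times, B was 3 and A 8 at 2 h, and C 1553. Without siNS 24 h arrays 2 and 3, A was 163 at 24 h. The replicate number is not known to pair cultures: 480 pairs of arrays with 1 number had a median correlation of residuals of 0.08, from -0.15 to 0.59, 200 of them over 0.1, against a median of -0.03 for other pairs. As a hint from the data that numbers share something, 54 of 64 arrays correlated best with their own number, and the counts without the block leave this out. Quantile normalization without background correction, a slide block and detection filters were not run, for want of a link between scanner columns and samples. Signal near background limits genes such as ATP4A and NEU4 to lower bounds.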

Other observations

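The test of a hormone response already present at 0 h was chosen before the result was seen.

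Of the lists, circadian genes had a camera call after hormone that was lost with an estimated correlation. At 4 h 5 of 13 circadian genes were lower in the average of both siRNAs, and 6 adjusted over the list alone (camera adjusted p = 0.03, and 0.14 with an estimated correlation), among them the repressors BHLHE40 and NR1D2 and the activator DBP with both siRNAs. The GR-induced members CEBPB and ERRFI1 were lower at 4 h, by -0.85 ± 0.14 and -1.08 ± 0.27 with siHic5_2 and -1.32 ± 0.14 and -1.44 ± 0.27 with siHic5_5. RUNX2, an osteoblast transcription factor and the 1 called member of 7 in its list, was lower at 4 h by -1.65 ± 0.35 and -1.78 ± 0.35. At 24 h the leukocyte integrin ITGB2, the 1 called member of 6, was higher by 2.11 ± 0.21 and 1.14 ± 0.21. These genes are list members and were chosen after their values were seen. With siHic5_5 alone 12 of 17 p53 targets were lower at 0 h than in siNS, which itself had 4 higher than NI (camera adjusted p = 0.00057, and 0.37 with an estimated correlation).

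Genes that depletion moved at 0 h overlap with genes that hormone moves in NI cells, a comparison that shares no arrays. Of the features called with siHic5_2 at 0 h and by hormone in NI at 4 h, 136 moved the same way and 68 the opposite way (85.8 and 86.1 for independent lists), and with siHic5_5 286 and 106 (156 and 157). Of the genes called with both siRNAs, 61 moved the same way and 14 the opposite way (23.1 and 22.1). At 24 h these were 230 and 80 (119 and 118). The nonspecific siRNA showed a similar lean, in features called in siNS against NI at 0 h and by hormone with both Hic-5 siRNAs. Of these, 10 moved the same way and 4 the opposite way at 4 h (6.12 and 6.09), and 50 and 13 at 24 h (21.0 and 20.9). The lean is therefore not particular to the Hic-5 siRNAs. Part of the hormone response may already be present in depleted cells without added hormone, for example through steroids in the 5% serum: the lowest share moving the same way over both siRNAs at 4 and 24 h was 60.7%, which neither shows nor excludes it. Serum steroids were not measured.

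The human receptor gene NR3C1 averaged 6.60 in NI, 6.66 in siNS, 6.59 with siHic5_2 and 5.74 with siHic5_5 at 0 h on its brightest probe, near background. The transfected receptor is the rat protein, so these human probes leave its level unknown. Of the 678 features called with both siRNAs at 0 h, 45 were also called in siNS against NI, all 45 in the opposite direction and 0 in the same (limma), as the siNS arrays enter both comparisons.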
